A study of Mus musculus with 10 samples.

How the data were processed

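Gene expression was measured by RNA sequencing in 10 mouse liver libraries: 4 of normal liver, 3 of Akt/Nras tumours and 3 of Akt/Nras/Foxo1AAA tumours. The groups and replicate numbers came from the sample titles. Per the labels' protocols, total RNA was extracted with a Quick-RNA Miniprep kit, and the library step is described as either polyA capture or removal of rRNA, without saying which. The authors deposited 1 table of FPKM values with 56748 genes and 1 column per library, per the file headers, and replicates were not pooled. FastQC 0.11.7 and the build GRCm38 are named in the submitters' processing notes with no role, and the aligner, the counter and the annotation release are not given in the sources used here. The coordinates in the deposited table belong to a build that is not named. Of 52073 genes of the GRCm38 annotation supplied with the data that the table also lists, 1472 had identical coordinates, so no GRCm38 coordinate was used. Every column of values belonged to a sample.

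FPKM are not counts, so the main test was a linear model on a log scale. The deposited FPKM multiplied by the gene length in the table gave whole reads, within 0.02 reads, for 100% of the values above 0. These recovered reads numbered 13.6 to 21.3 M per library, and 1 read over 1 kb was worth 0.0469 to 0.1135 FPKM. The number that each library's reads were divided by was not its summed reads. It was 0.629 to 0.668 of them in normal liver and 0.875 to 0.928 in Akt/Nras/Foxo1AAA tumours, and was nearest to them in Akt/Nras tumours. FPKM summed to 692009.9 to 743202.8 in normal liver, 349618.6 to 381653.1 in Akt/Nras tumours and 413812.4 to 444893 in Akt/Nras/Foxo1AAA tumours. The deposited values were not rescaled in the main test, and other scalings were run as alternatives.

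Of the 56748 genes 29302 were 0 in all libraries, and 959 shared a symbol with another gene. Genes with an FPKM of at least 1 in at least 3 of the 10 libraries were tested, which left 12439. The values were transformed as log2(FPKM + 1), so log2 changes are on that scale and understate the change of genes of low expression, whereas folds are ratios of mean FPKM. All 10 libraries entered 1 fit with a mean per group in limma 3.58.1 (lmFit, contrasts.fit and eBayes with a variance trend) in R 4.3.3, and the tests were two-sided. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. The 3 comparisons were each tumour group against normal liver and the tumour groups against each other. The groups shared 1 estimate of the spread because each holds only 3 or 4 libraries. Nothing in the labels says that replicates came from separate mice, nor that the same replicate number in different groups marks a shared litter, day or batch.

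Before the data were examined, 60 gene lists on liver function, metabolism, growth, signalling and markers of other cell types were fixed, with 1344 symbols, of which 2 were absent from the table. The 56 lists with at least 5 tested genes were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, whose directional test asks whether the genes of a list move, on balance, one way and does not compare the list with other genes. Calls of members were counted over all genes and adjusted over the list alone. The lists described were chosen after the list results were seen.

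The rule for named genes was fixed before the data were examined. It took a panel that includes Foxo1, Akt1, Akt2, Nras, Gsk3a, Gsk3b, Tsc1 and Tsc2 in every comparison. It also took, per comparison, the 8 called genes with the largest increase and the 8 with the largest decrease, among those with a log2 change of at least 1 in size, groups whose libraries did not overlap, a mean of at least 10 FPKM in the higher group and a symbol that is not a predicted model. From each described list it took up to 2 called members with the largest increase and up to 2 with the largest decrease, or the member with the highest mean where none was called. Some genes that the rule took are not reported here, and counts of named genes include them. Where 5 or fewer members of a described list were called in a direction, others were named too, after their values were seen. So were the 10 genes called with the 6 tumour libraries alone, the genes called in opposite directions, the abundant genes given with the tests of admixed tissue and of other cell types, the sex-linked genes, and G6pc and Igfbp1 in the comparison between tumour groups.

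Comparisons that share libraries share their chance values. Overlaps of the calls against normal liver and the covariance of log2 changes were therefore set beside 100 simulated draws with no effect. These overlaps were also set beside those of independent lists and the 6 ways of giving each tumour group 2 of the 4 normal livers. Overlaps with the calls between the tumour groups were set beside independent lists only. Other splits of the libraries of each comparison were refitted. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-of-ratios scaling, equal totals per library (TPM), scaling with the 50 most abundant genes left out, quantile normalization, only the 2 groups compared in the fit, no variance trend, array weights, the replicate number as a block, and leaving out each library in turn. A fit of limma-voom to the recovered reads was added after the data were seen.

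The fit was tested on simulated data with 12439 genes, of which 12239 were unchanged and 100 were changed by each size, per comparison. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2 in normal liver, and all groups had the same simulated spread. The shares recovered therefore do not cover genes of lower expression or groups of unequal spread. At a log2 size of 1 it recovered 90% of the changed genes in the layout of Akt/Nras tumours against normal liver, 91% in that of Akt/Nras/Foxo1AAA tumours against normal liver and 90% in that of the tumour groups. At a log2 size of 2 it recovered 99%, 98% and 97%, and it called 9, 13 and 10 unchanged genes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.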

Results

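RNA was sequenced from 10 mouse liver samples in 3 groups: 4 normal livers of wild-type FVB mice, 3 liver tumours raised with Akt and Nras (Akt/Nras tumours) and 3 liver tumours raised with Akt, Nras and Foxo1AAA (Akt/Nras/Foxo1AAA tumours). The tumours model hepatocellular carcinoma and were made by hydrodynamic tail vein injection, in which a fast injection of plasmid DNA into the tail vein delivers the DNA to hepatocytes. AKT is a growth-promoting kinase that phosphorylates and excludes from the nucleus the transcription factor FOXO1, and Foxo1AAA is a form whose AKT phosphorylation sites were changed to alanine so that AKT no longer inhibits it. The series concerns which AKT substrates, among them GSK3 and TSC2, carry its tumour-promoting activity. The whole reads behind the FPKM values numbered 13.6 to 17.5 M per normal liver, 16.2 to 21.3 M per Akt/Nras tumour and 15.4 to 20.7 M per Akt/Nras/Foxo1AAA tumour. The labels count the tumours and livers but do not say that each came from another mouse, so p-values measure the spread between these samples.

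The libraries separated by group. The first principal component of log2(FPKM + 1) over 12439 genes held 85.2% of the variance, with normal livers between -78.8 and -69.6, Akt/Nras/Foxo1AAA tumours between 27.1 and 45.9 and Akt/Nras tumours between 58.9 and 68.5. Across genes, which are not independent replicates, Pearson's r was 0.973 to 0.989 between libraries of a group and 0.755 to 0.815 between Akt/Nras tumours and normal livers. Reads from mitochondrially encoded genes made up 6.54% ± 0.99 (SD, n = 4) of the reads in normal liver, 2.39% ± 0.191 (SD, n = 3) in Akt/Nras tumours and 2.97% ± 0.521 (SD, n = 3) in Akt/Nras/Foxo1AAA tumours. Directions of small changes depended on the scaling. With every library rescaled to the same FPKM total, called equal totals here, the median log2 change of all genes moved from -0.07 to 0.78 for Akt/Nras tumours against normal liver, from -0.09 to 0.52 for Akt/Nras/Foxo1AAA tumours against normal liver and from -0.01 to -0.23 between the tumour groups.

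The injected genes were examined first. Foxo1 (ENSMUSG00000044167) stood at 95.4 ± 25.7 FPKM (SD, n = 3) in Akt/Nras/Foxo1AAA tumours, with libraries from 77.9 to 125 FPKM, against 5.81 ± 0.381 FPKM (SD, n = 3) in Akt/Nras tumours and 7.18 ± 0.572 FPKM (SD, n = 4) in normal liver. It was 16.4-fold higher than in Akt/Nras tumours (log2 change 3.79, SE 0.15, limma adjusted p = 2.44e-06) and 13.3-fold higher than in normal liver (log2 change 3.53, SE 0.14, limma adjusted p = 3.65e-08). Akt1 (ENSMUSG00000001729) was 41.6-fold higher in Akt/Nras tumours, at 880 ± 139 FPKM (SD, n = 3), than in normal liver, at 21.1 ± 0.442 FPKM (SD, n = 4; log2 change 5.30, SE 0.18, limma adjusted p = 8.05e-09). In Akt/Nras/Foxo1AAA tumours Akt1 reached 880 ± 280 FPKM (SD, n = 3), and the change between the tumour groups, -0.03 on the log2 scale with an SE of 0.19, did not pass (limma adjusted p = 0.927). Nras, the GTPase upstream of the ERK pathway, was 1.96-fold higher in Akt/Nras tumours (10.4 ± 0.724 FPKM, SD, n = 3; limma adjusted p = 2.59e-06) and 1.73-fold higher in Akt/Nras/Foxo1AAA tumours (9.23 ± 0.25 FPKM, SD, n = 3; limma adjusted p = 1.79e-05) than in normal liver (5.33 ± 0.332 FPKM, SD, n = 4). In the deposited coordinates, whose build is not named and which differ from GRCm38 for most genes, Foxo1 spans 52175757 to 52260642 on chromosome 3 and Akt1 spans 112620255 to 112641318 on chromosome 12. The labels do not give the species or sequence of the injected constructs, so these values do not separate construct mRNA from endogenous mRNA.

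Among the AKT substrates of the series title, Gsk3b, a glycogen synthase kinase 3 gene, was 1.61-fold higher in Akt/Nras tumours (7.36 ± 1.11 FPKM, SD, n = 3) than in normal liver (4.58 ± 0.901 FPKM, SD, n = 4; limma adjusted p = 0.00307) and 1.51-fold higher in Akt/Nras/Foxo1AAA tumours (6.92 ± 0.536 FPKM, SD, n = 3; limma adjusted p = 0.00743). Gsk3a, its paralog, stood at 15.9 ± 0.904, 16.2 ± 0.698 and 16.3 ± 0.466 FPKM in normal liver, Akt/Nras and Akt/Nras/Foxo1AAA tumours (SD, n = 4, 3 and 3) and was not called. With equal totals its log2 changes against normal liver were 0.96 and 0.74 and passed. Tsc2, the GTPase-activating subunit of the complex that restrains mTORC1, stood at 6.24 ± 0.516, 5.05 ± 0.476 and 5.36 ± 0.456 FPKM in the same groups. It was called lower in Akt/Nras tumours (log2 change -0.26, limma adjusted p = 0.0238), and this turned to 0.61 with equal totals. The call was lost without normal liver replicate 1 or 2 or without Akt/Nras replicate 2 or 3 (limma adjusted p of 0.0596, 0.0578, 0.0768 and 0.0867). Tsc1 and Akt2 were called lower in both tumour groups, and with equal totals their log2 changes in Akt/Nras tumours were -0.03 and 0.06. Between the tumour groups none of Akt1, Akt2, Nras, Gsk3a, Gsk3b, Tsc1 and Tsc2 was called by limma (lowest adjusted p 0.165). Nras was called lower with equal totals (log2 change -0.41) and with array weights (-0.19).

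**Figure D1:**
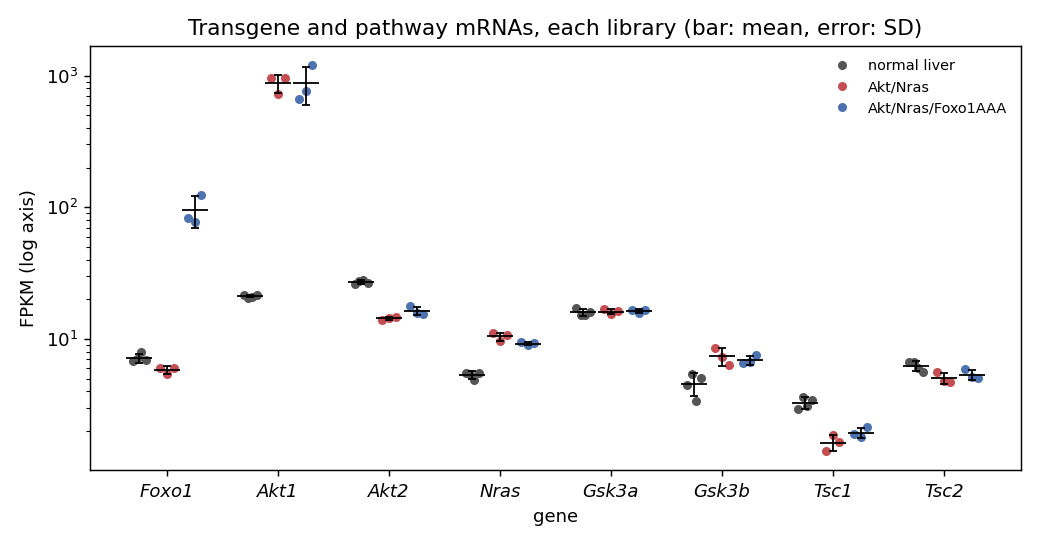
FPKM on a log axis of 8 genes fixed before the data were examined, each point 1 library, with bars at the group mean and error bars of 1 SD (normal liver n = 4, each tumour group n = 3). Foxo1 lies at 77.9 to 125 FPKM in Akt/Nras/Foxo1AAA tumours and at 5.37 to 8.02 FPKM in all other libraries, and Akt1 is 41.6-fold higher in both tumour groups than in normal liver.

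The first comparison asked which transcripts distinguished Akt/Nras tumours from normal liver. Markers of cholangiocytes and progenitors, of extracellular matrix and of monocytes and macrophages were higher in the tumours, and genes of cytochrome P450 drug metabolism, amino acid catabolism and oxidative phosphorylation were lower. Lcn2, an iron-binding protein of the acute phase, rose 713-fold to 2610 ± 212 FPKM (SD, n = 3; limma adjusted p = 3.42e-08). Spp1, which encodes osteopontin, rose 297-fold to 5030 ± 905 FPKM (SD, n = 3; limma adjusted p = 3.64e-09). The surface protein Ly6d rose 845-fold to 460 ± 161 FPKM and Cd14, a lipopolysaccharide co-receptor, 193-fold to 313 ± 7.23 FPKM (SD, n = 3). The tetraspanin Tspan8, the protease inhibitor Slpi, the carboxypeptidase Cpe and the steroid dehydrogenase Akr1c18 rose 550-fold, 116-fold, 177-fold and 480-fold, to 132 ± 29.2, 397 ± 73.1, 107 ± 18.7 and 78.4 ± 11.5 FPKM (SD, n = 3). At the other end Ces3b, a carboxylesterase, was 693-fold lower, at 0.566 ± 0.495 FPKM (SD, n = 3) against 392 ± 46.8 FPKM (SD, n = 4; limma adjusted p = 2.12e-08). The remaining large decreases were of major urinary proteins, pheromone carriers secreted by male liver, with Mup7 at 1.68 ± 1.77 FPKM against 8210 ± 1130 FPKM and Mup12 at 24.3 ± 20.4 FPKM against 17700 ± 5000 FPKM. Mup15, Mup17, Mup19, Mup21 and Mup22 fell too, and all Mup values are uncertain because reads of these near-identical genes can be split between copies. In each of these 16 genes the libraries of the groups did not overlap, because the rule that picked them required it.

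Among markers of other cell types, each of 14 measured cholangiocyte and progenitor genes rose, over all genes and adjusted over the list alone (camera adjusted p = 2.18e-08, adjusted p = 0.173 with an estimated correlation). Spp1 and Tspan8 led them. Of these 14 genes 5 had at least 1 FPKM in normal liver and 6 stood on another list, and the other 9 had a mean below 1 FPKM in normal liver. Of 25 extracellular matrix genes 24 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.64e-11, adjusted p = 0.173 with an estimated correlation). Of the 25, 13 had at least 1 FPKM in normal liver and 10 stood on another list. The collagen chain Col1a1 rose from 1.83 ± 0.52 FPKM (SD, n = 4) to 61.5 ± 2.91 FPKM (SD, n = 3), and the protease inhibitor Timp1 rose 173-fold. Dcn, a small leucine-rich proteoglycan, was the member that fell, from 21.1 ± 2.88 to 13.9 ± 0.772 FPKM, and its log2 change turned from -0.56 to 0.37 with equal totals. Each of 15 monocyte and macrophage markers rose, also adjusted over the list alone (camera adjusted p = 1.46e-06, adjusted p = 0.264 with an estimated correlation). Of these 15 genes 10 had at least 1 FPKM in normal liver and 2 stood on another list, Spp1 among them.

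Tumour, growth and signalling groups rose as well. Of 21 oncofetal and liver tumour markers 17 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.13e-06, adjusted p = 0.264 with an estimated correlation). Of the 21, 10 had at least 1 FPKM in normal liver and 7 stood on another list. Ly6d and Akr1c18 led them, and Tff3, a secreted mucosal peptide, fell from 5.25 ± 2.55 FPKM (SD, n = 4) to 1.03 ± 0.822 FPKM (SD, n = 3). Of 17 transcripts induced by RAS and ERK signalling 14 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.35e-05, adjusted p = 0.304 with an estimated correlation). Of the 17, 10 had at least 1 FPKM in normal liver and 3 stood on another list. Ier3, an immediate early gene, rose 90.2-fold and Dusp4, a phosphatase that acts on ERK, 41.4-fold, whereas Phlda1 fell from 51.8 ± 16.7 to 7.19 ± 0.0744 FPKM. Of 21 mitosis genes 20 rose, also adjusted over the list alone (camera adjusted p = 4.39e-05, adjusted p = 0.427 with an estimated correlation). The list's call was lost with equal totals (camera adjusted p = 0.0637), and 10 of the 21 had at least 1 FPKM in normal liver. The list's mean, on the log2 scale relative to normal liver, was 0.77, 1.84 and 1.76 in Akt/Nras replicates 1, 2 and 3 and 0.58 in normal liver replicate 1, and 19 to 21 genes rose with single libraries left out. The B-type cyclin Ccnb2 rose from 1.98 ± 2.05 FPKM (SD, n = 4) to 11 ± 3.94 FPKM (SD, n = 3), and Cdc20, an activator of the anaphase-promoting complex, rose 4.55-fold.

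Metabolic genes of the hepatocyte fell. Of 25 cytochrome P450 drug metabolism genes 22 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 4.65e-07, adjusted p = 0.264 with an estimated correlation). Cyp2e1 fell from 6620 ± 495 FPKM (SD, n = 4) to 65.7 ± 51.4 FPKM (SD, n = 3) and Cyp2c29 from 1390 ± 127 to 9.05 ± 6.46 FPKM. The fatty acid hydroxylase Cyp4a14 was the member that rose, from 1.05 ± 0.524 to 2.92 ± 1.41 FPKM (limma adjusted p = 0.0226), a call lost without normal liver replicate 2 (0.0586) or Akt/Nras replicate 2 (0.105). Of 25 amino acid catabolism genes 24 fell, also adjusted over the list alone (camera adjusted p = 2.18e-08, adjusted p = 0.264 with an estimated correlation). Among them Hpd of tyrosine breakdown was 25.6-fold lower and Haao of tryptophan breakdown 18.3-fold lower. All 28 nuclear genes of oxidative phosphorylation fell, also adjusted over the list alone (camera adjusted p = 2.32e-09, adjusted p = 0.279 with an estimated correlation), beside the lower share of mitochondrially encoded reads given above. Sdhb of complex II was 3.76-fold lower and Cox6c of complex IV 3.24-fold lower, and with equal totals 18 of the 28 fell and 2 rose. Of 25 glycolysis genes 16 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.34 with an estimated correlation). The list's call was lost with equal totals (camera adjusted p = 0.27) and with the 50 most abundant genes left out of the scaling (0.149). The members that rose most were Pfkp and Pkm, the platelet phosphofructokinase and muscle pyruvate kinase, 33.9-fold and 7.69-fold higher, and the liver pyruvate kinase Pklr was 4.05-fold lower.

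FOXO targets moved in both directions. Of 29 measured genes 19 fell and 7 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0246, adjusted p = 0.361 with an estimated correlation). With equal totals 11 fell and 11 rose. G6pc, the glucose-6-phosphatase of gluconeogenesis, was 12.9-fold lower and Pck1, its phosphoenolpyruvate carboxykinase, 4.26-fold lower. Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, rose from 26.7 ± 10.6 FPKM (SD, n = 4) to 369 ± 161 FPKM (SD, n = 3; limma adjusted p = 0.000173), and Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose 2.45-fold.

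Over all 12439 genes limma called 8587 between Akt/Nras tumours and normal liver, 3871 higher and 4716 lower in the tumours, and of these 1675 and 1924 changed by at least 1 on the log2 scale. With equal totals 8614 were higher and 1714 lower (4805 and 934 by at least 1), and with the 50 most abundant genes left out of the scaling 7489 were higher and 2195 lower (3096 and 1000 by at least 1). With a minimum of 5 FPKM 5372 genes were called. Of 56 lists with at least 5 measured genes camera called 18 higher and 22 lower, and 0 held with an estimated correlation, where 8 had an unadjusted p under 0.05, while fry called 47.

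The second comparison set Akt/Nras/Foxo1AAA tumours against normal liver. The largest increases were again of Lcn2, Ly6d, Spp1, Cd14, Tspan8, Akr1c18 and Slpi, joined by Cyp2a4, a steroid hydroxylase of female liver. Lcn2 was 633-fold higher, at 2320 ± 915 FPKM (SD, n = 3; limma adjusted p = 7.9e-08), and Spp1 233-fold higher, at 3950 ± 1360 FPKM (SD, n = 3; limma adjusted p = 7.44e-09). Ly6d, Cd14, Tspan8, Akr1c18 and Slpi were 1160-fold, 173-fold, 509-fold, 504-fold and 81.1-fold higher. Cyp2a4 rose from 0.817 ± 1 FPKM (SD, n = 4) to 182 ± 97.6 FPKM (SD, n = 3; limma adjusted p = 3.81e-07), a value uncertain for reads shared with its close paralogs. Hsd3b5, a steroid dehydrogenase of male liver, fell from 247 ± 27.0 to 0.0629 ± 0.0153 FPKM (limma adjusted p = 4.27e-11), and Serpina4-ps1, a serpin pseudogene, was 596-fold lower. The other large decreases were of Mup7, Mup15, Mup17, Mup19, Mup21 and Mup22, with Mup7 at 45.4 ± 72.9 FPKM and Mup21 at 15.1 ± 13.1 FPKM, uncertain as above. In each of these genes the libraries of the groups did not overlap, because the rule that picked them required it.

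Interferon-stimulated genes rose against normal liver in these tumours. Of 20 measured genes 13 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000796, adjusted p = 0.372 with an estimated correlation). The list was not called for Akt/Nras tumours, in which 6 rose and 5 fell, and 6 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.903, adjusted p = 0.98 with an estimated correlation). With equal totals 14 rose and 1 fell there, and the difference between the tumour groups was tested in the third comparison. Oas1a, a sensor of double-stranded RNA, was 11.7-fold higher and Usp18, a deubiquitinase-family protein that dampens interferon signalling, 4.44-fold higher, and the antiviral GTPase Mx2 fell from 2.18 ± 0.32 FPKM (SD, n = 4) to 1.13 ± 0.492 FPKM (SD, n = 3). Of 25 cytochrome P450 genes 21 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 9.67e-05, adjusted p = 0.287 with an estimated correlation). Cyp2c29 was 32.9-fold lower and Cyp1a2 31-fold lower. Cyp2b9, Cyp4a14 and Cyp4a10 were the members that rose, Cyp2b9 from 2.79 ± 0.972 to 7.88 ± 2.08 FPKM, and the call of Cyp4a14 was lost without Akt/Nras/Foxo1AAA replicate 3 (limma adjusted p = 0.0588). Of 29 FOXO targets 19 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0327, adjusted p = 0.372 with an estimated correlation). With equal totals 8 fell and 10 rose. G6pc was 12.3-fold lower and the transcription factor Klf15 4-fold lower, at 23 ± 3.09 FPKM (SD, n = 3), while Igfbp1, Gadd45a, Pik3ip1 and Sesn3 rose, Gadd45a 2.38-fold.

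Of 21 mitosis genes 9 rose over all genes (camera adjusted p = 0.00632, adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone limma called 0, with 11 higher at an unadjusted p under 0.05. The list's mean in normal liver replicate 1, 0.58, lay within the Akt/Nras/Foxo1AAA range of 0.48 to 0.95. Over all genes the members called were 2 without Akt/Nras/Foxo1AAA replicate 2, 5 without its replicate 3, 6 without its replicate 1, 3, 4 and 3 without normal liver replicates 2, 3 and 4, and 16 without normal liver replicate 1. The list was not called by limma's fry (adjusted p = 0.112) or with equal totals (camera adjusted p = 0.304). Nor was it called with the 50 most abundant genes left out (camera adjusted p = 0.264) or after quantile normalization (0.0631). Limma itself called 18 of its genes higher with equal totals, 18 with the 50 genes left out and 2 after quantile normalization. The kinase Plk1 rose from 1.62 ± 1.75 to 4.35 ± 1.73 FPKM (limma adjusted p = 0.0464) and the ubiquitin-conjugating enzyme Ube2c from 2.48 ± 1.88 to 5.87 ± 1.39 FPKM (limma adjusted p = 0.0444). Both calls were lost without normal liver replicate 2, 3 or 4 and without Akt/Nras/Foxo1AAA replicate 2 or 3, where the limma adjusted p reached 0.149 for Plk1 and 0.136 for Ube2c. That of Plk1 was also lost without Akt/Nras replicate 2 (0.0502) or 3 (0.0569), and that of Ube2c without Akt/Nras/Foxo1AAA replicate 1 (0.0629). Of 77 cytosolic ribosomal protein genes 54 fell and 2 rose, and adjusted over the list alone 55 fell and 2 rose (camera adjusted p = 9.77e-05, adjusted p = 0.521 with an estimated correlation). This direction depended on the scaling. With equal totals 37 rose and 1 fell and the list's call was lost (camera adjusted p = 0.568), and after quantile normalization camera called the list higher (camera adjusted p = 0.00138). Rpl35a was 4.56-fold lower and Rps29 1.96-fold lower, and Rps4l and Rpl13a rose 2.39-fold and 1.53-fold. The call of Rpl13a was lost without normal liver replicate 2 (limma adjusted p = 0.0582) or Akt/Nras/Foxo1AAA replicate 2 (0.0801) or 3 (0.0733), and ribosomal protein values are uncertain for reads shared with pseudogenes. Of 7 red blood cell genes 5 rose, also adjusted over the list alone (among them Hbb-bt, Hbb-bs, Hba-a1 and Bpgm; camera adjusted p = 0.0327, adjusted p = 0.424 with an estimated correlation). The list's call was lost without Akt/Nras/Foxo1AAA replicate 2 (camera adjusted p = 0.0584) and with equal totals (0.218), and its mean in normal liver replicate 1, 0.58, lay above that in Akt/Nras/Foxo1AAA replicate 1, 0.5. Hbb-bs, an adult beta globin, rose from 445 ± 119 to 1100 ± 317 FPKM and the near-identical Hbb-bt from 93.4 ± 26.1 to 232 ± 66.3 FPKM.

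Limma called 7874 of 12439 genes in this comparison, 3330 higher and 4544 lower, of which 1332 and 1475 changed by at least 1 on the log2 scale. With equal totals 7613 were higher and 1678 lower (3180 and 727 by at least 1), and with the 50 most abundant genes left out of the scaling 6845 were higher and 1916 lower (2306 and 705 by at least 1). With a minimum of 5 FPKM 5027 genes were called. Of the 56 lists camera called 22 higher and 22 lower, and 0 held with an estimated correlation, where 10 had an unadjusted p under 0.05, while fry called 49. In both tumour groups 3079 genes were called higher and 4080 lower than in normal liver, and 7 were called in opposite directions. Independent lists of these sizes would share 1036 and 1723 genes, and 100 simulations of unchanged groups against the shared normal livers gave at most 0 and 1. Unchanged groups give few calls to overlap, so the simulations cannot show how far the shared livers raise the overlap of such long lists. With different normal livers for each tumour group, over 6 ways of splitting them, 2617 to 2718 genes were higher and 3488 to 3558 lower in both, against 813 to 858 and 1373 to 1430 for independent lists.

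The third comparison set Akt/Nras/Foxo1AAA tumours against Akt/Nras tumours. The sources used here do not give the time of collection, so a difference in it between the groups cannot be told apart from an effect of Foxo1AAA. Transcripts of hepatocyte products and metabolism were higher in Akt/Nras/Foxo1AAA tumours, interferon-stimulated genes were higher, and cholangiocyte and matrix genes were lower. After Foxo1 itself, the largest increases were of Mup12, 13.6-fold to 329 ± 308 FPKM, and of Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, 15.3-fold to 29.9 ± 21.6 FPKM (SD, n = 3; limma adjusted p = 0.0165 and 0.00327). Cyp2e1 rose 5.97-fold to 392 ± 61.0 FPKM (SD, n = 3), still below its normal level, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 1.07 ± 1.11 to 11.2 ± 4.73 FPKM (SD, n = 3; limma adjusted p = 0.00586). Rdh16f2, a retinol dehydrogenase family member, Mup20 and the pseudogene Mup-ps19 rose 10.6-fold, 6.09-fold and 8.56-fold. Krt19, a keratin of bile duct cells, was 9.27-fold lower, at 1.77 ± 0.391 FPKM against 16.4 ± 11 FPKM (SD, n = 3; limma adjusted p = 0.00554). Sprr1a, a cornified envelope protein, was 6.2-fold lower, the activin antagonist Fstl3 5.4-fold, the metalloproteinase Mmp7 5.02-fold, the tight junction protein Cldn7 4.29-fold, the protease inhibitor A2m 4-fold and Anxa3, an annexin, 3.73-fold. Without single libraries limma lost the call of A2m (any library but Akt/Nras/Foxo1AAA replicate 3, adjusted p up to 0.141), of Cldn7 (Akt/Nras replicate 1 or 3 or Akt/Nras/Foxo1AAA replicate 2, up to 0.0932) and of Mup12 (Akt/Nras replicate 1 or Akt/Nras/Foxo1AAA replicate 1 or 2, up to 0.0565). The calls of Anxa3, Mup20 and Mup-ps19 were lost without Akt/Nras/Foxo1AAA replicate 1 or 2 (limma adjusted p up to 0.0677, 0.0532 and 0.0596) and that of Cyp2e1 without replicate 1 (0.053). Libraries of the tumour groups did not overlap in any of these genes, because the rule that picked them required it. For a single gene chance gives this in 10% of cases with 3 against 3.

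Hepatocyte groups rose together. Of 25 cytochrome P450 drug metabolism genes 16 rose, and 20 adjusted over the list alone (camera adjusted p = 2.29e-13, adjusted p = 0.17 with an estimated correlation). Of 30 plasma protein and coagulation genes 20 rose, and 24 adjusted over the list alone (camera adjusted p = 2.29e-13, adjusted p = 0.243 with an estimated correlation). The apolipoproteins Apoa1 and Apoa2 were 2.29-fold and 2.27-fold higher. Of 20 bile acid genes 14 rose, and adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 3.51e-11, adjusted p = 0.17 with an estimated correlation). Cyp8b1 and Cyp7a1 led them. Of 25 amino acid catabolism genes 16 rose, and 19 adjusted over the list alone (camera adjusted p = 1.19e-10, adjusted p = 0.294 with an estimated correlation). Hpd rose from 56.2 ± 44.5 to 182 ± 48.7 FPKM (SD, n = 3) and Bhmt, a methyltransferase of homocysteine metabolism, from 115 ± 43.9 to 376 ± 165 FPKM. Of 24 lipogenic genes 10 rose, and 16 adjusted over the list alone (camera adjusted p = 9.77e-07, adjusted p = 0.341 with an estimated correlation). Fasn, the fatty acid synthase, was 2.83-fold higher and Thrsp, a regulator of lipogenesis, 2.66-fold higher. Beside these groups, 3 of 7 red blood cell genes rose, Alas2 and Bpgm among them, and 6 adjusted over the list alone (camera adjusted p = 0.000745, adjusted p = 0.367 with an estimated correlation). The tumour groups overlapped in this list's mean, at -0.24, -0.26 and 0.58 in Akt/Nras replicates 1, 2 and 3 and 0.5, 1.55 and 1.05 in Akt/Nras/Foxo1AAA replicates 1, 2 and 3. Its genes called by limma numbered 0 without replicate 2 of either tumour group, 1 without Akt/Nras replicate 1, 5 without Akt/Nras replicate 3 and 2 or 3 without any of the other libraries. Alas2 of heme synthesis was 2.17-fold higher. Limma lost the call of Fasn without any library but normal liver replicate 3, Akt/Nras replicate 2 and Akt/Nras/Foxo1AAA replicate 3 (adjusted p up to 0.149), of Apoa2 without Akt/Nras replicate 1 or Akt/Nras/Foxo1AAA replicate 1 or 2 (0.0604) and of Hpd without replicate 1 of either tumour group (0.0675). That of Thrsp was lost without Akt/Nras/Foxo1AAA replicate 1 or 2 (limma adjusted p up to 0.0593) and that of Alas2 without Akt/Nras replicate 1 or 2 or Akt/Nras/Foxo1AAA replicate 2 (0.0768).

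Of 20 interferon-stimulated genes 14 rose, and 18 adjusted over the list alone (camera adjusted p = 9.38e-10, adjusted p = 0.313 with an estimated correlation). Iigp1, an immunity-related GTPase, rose from 23.3 ± 3.96 to 51.1 ± 6.76 FPKM (SD, n = 3; limma adjusted p = 0.00327) and Ifit3 from 2.96 ± 0.672 to 7.21 ± 2.60 FPKM (limma adjusted p = 0.0416). The members called fell to 4 without Akt/Nras/Foxo1AAA replicate 1 and to 3 without replicate 2, while the list's median log2 change of 0.69 became 0.59 and 0.65. Of 15 monocyte and macrophage markers 1 fell, also adjusted over the list alone (Cd44, a hyaluronan receptor, from 10.5 ± 2 to 3.93 ± 2.50 FPKM), and the list was not called (camera adjusted p = 0.291, adjusted p = 0.642 with an estimated correlation). Of 14 Kupffer cell markers C6, Cd5l and Folr2 rose, and 4 genes adjusted over the list alone (camera adjusted p = 0.00698, adjusted p = 0.453 with an estimated correlation). The list was not called by limma's fry (adjusted p = 0.117), with a minimum of 5 FPKM (camera adjusted p = 0.17) or with array weights (0.084). The list's mean was 0.08 in Akt/Nras replicate 3 and 0.06 in Akt/Nras/Foxo1AAA replicate 3, so the groups overlapped, and limma called 0 members without Akt/Nras replicate 1 or Akt/Nras/Foxo1AAA replicate 1 or 2. The complement component C6 rose 3.6-fold and Cd5l, a secreted macrophage protein, 2.33-fold, and C6 is also made by hepatocytes. Limma lost the call of Ifit3 without any library but normal liver replicate 3 and Akt/Nras/Foxo1AAA replicate 3 (adjusted p up to 0.145) and of Cd5l without any but normal liver replicate 3 and Akt/Nras replicate 3 (0.14). The calls of Cd44 and C6 were lost without Akt/Nras replicate 1 or Akt/Nras/Foxo1AAA replicate 1 or 2 (limma adjusted p up to 0.0673 and 0.0762).

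Of 14 cholangiocyte and progenitor markers 8 fell, and 11 adjusted over the list alone (camera adjusted p = 5.67e-08, adjusted p = 0.17 with an estimated correlation). Among them were Krt19 and Cftr, an epithelial chloride channel, at 0.779 ± 0.418 FPKM against 7.32 ± 1.34 FPKM (SD, n = 3; limma adjusted p = 0.000306). Of 25 matrix genes 8 fell, and 15 adjusted over the list alone (camera adjusted p = 9.61e-08, adjusted p = 0.243 with an estimated correlation). With equal totals 19 fell, and 13 with the 50 most abundant genes left out of the scaling. The collagen cross-linking enzymes Lox and Loxl2 were 2.8-fold and 2.34-fold lower. Of 14 hypoxia genes 4 fell, Egln3, Ndrg1, Slc2a1 and Ero1a, and 9 adjusted over the list alone (camera adjusted p = 2.27e-05, adjusted p = 0.367 with an estimated correlation). The tumour groups overlapped in this list's mean, at 1.66, 0.86 and 1.38 in Akt/Nras replicates 1, 2 and 3 and 0.05, 0.46 and 0.93 in Akt/Nras/Foxo1AAA replicates 1, 2 and 3. Limma called 0 of its genes without Akt/Nras/Foxo1AAA replicate 1 or 2, 1 and 2 without Akt/Nras replicates 3 and 1, and 8 without Akt/Nras/Foxo1AAA replicate 3. With equal totals limma called 10 of the hypoxia genes lower, and 8 with the 50 most abundant genes left out of the scaling. Egln3, a prolyl hydroxylase induced by hypoxia, was 2.84-fold lower and Ndrg1 4.2-fold lower. Of 77 ribosomal protein genes 12 fell, and 39 adjusted over the list alone (camera adjusted p = 7.02e-13, adjusted p = 0.383 with an estimated correlation). With equal totals 64 fell, with the 50 most abundant genes left out 52, after quantile normalization 59 and with median-of-ratios scaling 9. Rps27a was 1.92-fold and Rpl21 1.53-fold lower, values uncertain as above. For 21 mitosis genes limma called 0, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 15 of the 21 were lower. With equal totals limma called 11 of the 21 lower, and 5 with the 50 most abundant genes left out of the scaling. Camera called this list lower (adjusted p = 1.66e-06, adjusted p = 0.414 with an estimated correlation) and fry did not (adjusted p = 0.105). The list's mean in Akt/Nras replicate 1, 0.77, lay within the Akt/Nras/Foxo1AAA range of 0.48 to 0.95, and without this library limma called 15 of the genes lower. Cdc20 stood at 6.58 ± 2.37 FPKM against 15.6 ± 6.83 FPKM (SD, n = 3; limma adjusted p = 0.143). Limma lost the call of Egln3 without any library but Akt/Nras/Foxo1AAA replicate 3 (adjusted p up to 0.116) and of Loxl2 and Ndrg1 without Akt/Nras/Foxo1AAA replicate 1 or 2 (0.0803 and 0.0593). That of Rps27a was lost without any library but normal liver replicate 1 or 2 and Akt/Nras replicate 1 (limma adjusted p up to 0.136), and that of Rpl21 without normal liver replicate 4, Akt/Nras replicate 1 or 2 or Akt/Nras/Foxo1AAA replicate 1 or 2 (0.0922).

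Of 29 FOXO targets 4 rose, Apoc3, Abca6, Gabarapl1 and Mttp, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.0435, adjusted p = 0.452 with an estimated correlation). Apoc3, an apolipoprotein, was 1.94-fold higher and the transporter Abca6 1.62-fold higher. Without Akt/Nras/Foxo1AAA replicate 1 or 2 limma lost both calls, that of Apoc3 also without Akt/Nras replicate 1 or 2 (adjusted p up to 0.0989) and that of Abca6 without Akt/Nras replicate 2 or 3 (0.105). G6pc stood at 13.7 ± 3.64 FPKM against 13.1 ± 2.51 FPKM and Igfbp1 at 398 ± 401 FPKM against 369 ± 161 FPKM (SD, n = 3), neither called. The list was not called by limma's fry (adjusted p = 0.0709), with a pseudocount of 0.1 (camera adjusted p = 0.0536), with a minimum of 5 FPKM (0.114), with median-of-ratios scaling (0.0549) or with array weights (0.26). Nor was it called without Akt/Nras replicate 2 (camera adjusted p = 0.184) or Akt/Nras/Foxo1AAA replicate 1 (0.0828) or 3 (0.0918), and its median log2 change of 0.20 became -0.04 with equal totals. The groups overlapped in the list's mean (-0.54 in Akt/Nras replicate 1, -0.55 in Akt/Nras/Foxo1AAA replicate 2). Limma called 0 members without Akt/Nras/Foxo1AAA replicate 1, and 2 or fewer without its replicate 2 or Akt/Nras replicate 1 or 2.

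**Figure D2:**
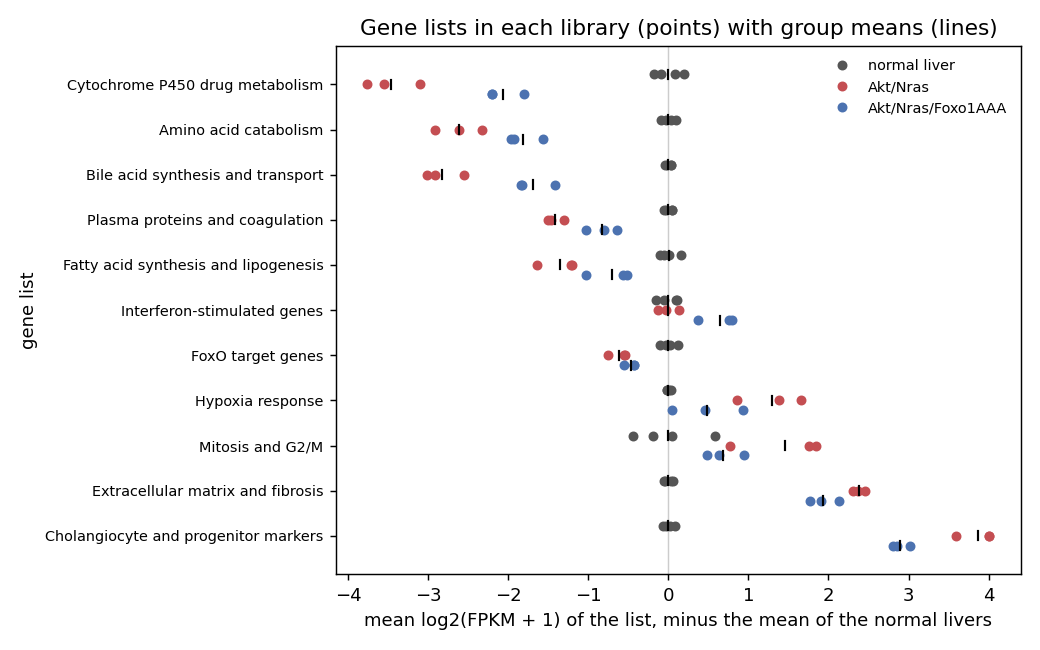
Mean log2(FPKM + 1) of the measured genes of 11 lists, minus the mean of the normal livers, on the horizontal axis, each point 1 library and each vertical line a group mean (normal liver n = 4, each tumour group n = 3). For cytochrome P450 genes the Akt/Nras tumours lie at -3.76 to -3.1 and the Akt/Nras/Foxo1AAA tumours at -2.2 to -1.8, and for interferon-stimulated genes at -0.13 to 0.13 and at 0.37 to 0.8.

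Limma called 1500 of 12439 genes between the tumour groups, 986 higher and 514 lower in Akt/Nras/Foxo1AAA tumours, of which 225 and 69 changed by at least 1 on the log2 scale. The latter counts were 187 and 298 with equal totals, 199 and 123 with the 50 most abundant genes left out, and 110 and 39, 166 and 42, and 336 and 131 without Akt/Nras/Foxo1AAA replicate 1, 2 and 3. Of the 986 higher genes 867 were lower in Akt/Nras tumours than in normal liver, against 374 for independent lists. Of the 514 lower genes 438 were higher there, against 160. Both calls use the Akt/Nras libraries, so independent lists understate what chance gives, and these counts were not simulated. Across genes, the covariance of the log2 change between tumour groups with that of Akt/Nras tumours against normal liver was -0.321 (r = -0.65), where the shared Akt/Nras libraries alone gave -0.0191 in simulations (r = -0.53), a difference of -0.302. Of the 56 lists camera called 25 higher and 9 lower, and 0 held with an estimated correlation, where 8 had an unadjusted p under 0.05, while fry called 28. This comparison depended on the fit. With only the 6 tumour libraries limma called 10 genes, with 3107 at an unadjusted p under 0.05. These were Foxo1, Cyp2c50, Sult2a8, Inmt and Fam83a higher and Sprr1a, Cftr, Adamts1, Mir1932 and ENSMUSG00002076241 lower, and 36 of the 47 genes named for this comparison lost their call in that fit. Of the 47 genes 22 lost their call without Akt/Nras/Foxo1AAA replicate 1, 23 without its replicate 2 and 16 without Akt/Nras replicate 1. The 47 include Akt1, Akt2, Nras, Gsk3a, Gsk3b, Tsc1, Tsc2 and Cdc20, which were not called and had no call to lose. In all, limma called 901 without Akt/Nras replicate 1, 550 and 632 without Akt/Nras/Foxo1AAA replicates 1 and 2, 923 with no filter and 3668 with array weights. The split turned to 650 higher and 3015 lower with equal totals, 803 and 1239 with the 50 most abundant genes left out and 966 and 847 after quantile normalization.

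**Figure D3:**
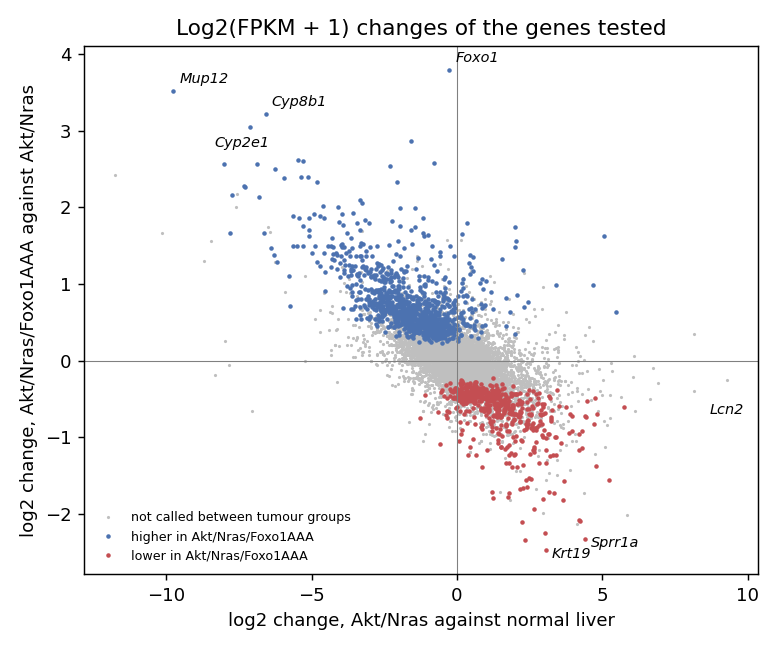
Each point is 1 of 12439 genes, with its log2(FPKM + 1) change in Akt/Nras tumours against normal liver on the horizontal axis and in Akt/Nras/Foxo1AAA against Akt/Nras tumours on the vertical axis, and colours mark the 986 genes called higher and the 514 called lower between the tumour groups. Of the higher genes 867 were called lower in Akt/Nras tumours than in normal liver, and both axes share the Akt/Nras libraries, which alone gives a negative covariance.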

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

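All tests in this part were chosen after the results were seen, except the one that leaves out single libraries for the interferon-stimulated genes.

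In normal liver, 5 of 113 groups of values had 1 library far from the other 3, and chance gives about 1 in 20. Col1a1 was 2.6 FPKM in replicate 1 against 1.49 to 1.61 FPKM in the others. Ccnb2 was 5.02 FPKM in replicate 1 against 0.582 to 1.3 FPKM. Dcn was 25.5 FPKM in replicate 4 against 19.5 to 20 FPKM. In replicate 2, Cyp2a4 was 2.31 FPKM against 0.197 to 0.522 FPKM and Acot3 was 8.69 FPKM against 2.1 to 3.06 FPKM.

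Called in opposite directions against normal liver, 7 genes also had a called difference between the tumour groups. Prg4 stood at 14.3 ± 1.95 FPKM in normal liver (SD, n = 4), 8.66 ± 2.6 FPKM in Akt/Nras tumours (SD, n = 3) and 20.2 ± 2.04 FPKM in Akt/Nras/Foxo1AAA tumours (SD, n = 3), with a log2 difference of 1.17 between the tumour groups (limma adjusted p = 0.00711). Irf7, a transcription factor of the interferon response, stood at 6.91, 4.98 and 10.2 FPKM on average, with a difference of 0.89 (limma adjusted p = 0.0113). The differences were 1.64 for H2-Q1 and 1.36 for Klk1b4, whose reads can be split with close paralogs. They were -0.41 for Rad21, -0.54 for Zbtb12 and -0.47 for Rif1. Against normal liver the log2 changes in Akt/Nras and Akt/Nras/Foxo1AAA tumours were small, at 0.2 and -0.21 for Rad21, and reached -1 and 0.64 for H2-Q1. Equal totals moved the median of all genes from -0.07 to 0.78 and from -0.09 to 0.52 in these comparisons. The opposite directions may therefore depend on the scaling.

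Hepatocyte genes were among 867 genes called higher in Akt/Nras/Foxo1AAA than in Akt/Nras tumours and lower in Akt/Nras tumours than in normal liver. The 867 were taken by these calls alone, whatever cells express them, and also include Irf7, H2-Q1, Prg4 and Klk1b4. Normal tissue mixed into the samples brings all its abundant transcripts, and in 6 mixtures simulated from these libraries, with 5 to 40% of normal liver, 0 or 1 gene lay below the bound described next. The lower quartile of the normal share that the 867 genes imply was 15.2% (median 24.9%), while 53 of 746 genes of at least 100 FPKM in normal liver (7.1%) lay below 15.2% of their normal level in all 3 libraries (22 of them outside the 867, and 33 of 721 with male-biased and Mup genes left out), among them Mup22 (0.214%), Hamp (3.06%), Cyp2e1 (5.93%) and Fabp1 (9.25%), which argues against admixture as the whole cause. The scaling is also argued against as the whole cause, since 544 of the 867 (62.7%) were still called higher with equal totals, the fewest of 4 other scalings. An effect of Foxo1AAA on hepatocyte transcripts remains a hypothesis. A smaller admixture of liver like these normal livers is bounded by genes such as Hsd3b5, at 0.0254% of its normal level, and Serpina4-ps1, at 0.168%. These values lie far below 15.2% and argue against such an admixture beside it. Admixed liver that itself holds less of these transcripts was not simulated and stays open.

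Male-biased liver genes were lower and female-biased liver genes higher in Akt/Nras tumours than in normal liver. Female mice in the tumour groups are argued against by Ddx3y, a Y-linked gene, at 7.87 FPKM or more in all 6 tumour libraries, and by Xist at 0.0123 FPKM at most. The median log2 change of the female-biased genes, 1.16, decides nothing on a general loss of hepatocyte RNA, because 5 of the 11 had at least 1 FPKM in normal liver and the others could hardly fall. For the male-biased part such a loss lowers the genes about as far as other hepatocyte genes. Their upper quartile was -3.31, below the lower quartile of 68 genes of plasma proteins, amino acid catabolism and the urea cycle, -2.71. This argues against a loss of the size seen in these 68 genes. The 25 genes of cytochrome P450 drug metabolism were left out of that comparison. They had a median of -3.16, against -1.97 for the 68 genes and -4.14 for the male-biased genes. A loss as large as that of the cytochrome P450 genes stays open. A change in the hormonal control of the male-biased and female-biased genes may be involved and was not tested.

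Interferon-stimulated genes were higher in Akt/Nras/Foxo1AAA than in Akt/Nras tumours, with a median log2 change of 0.69. More infiltrating myeloid cells are argued against, as far as markers of monocytes and macrophages follow such cells. The list of these markers had a median of -0.16 and an upper quartile of 0.09. Of its 15 genes 10 had at least 1 FPKM in normal liver and 2 stood on another list. Its most abundant genes Spp1, Cd14 and Lyz2 stood at 5030, 313 and 121 FPKM in Akt/Nras tumours. In Akt/Nras/Foxo1AAA tumours they stood at 3950, 280 and 105 FPKM. Spp1 also stands on the cholangiocyte and progenitor list, where 8 of 14 genes fell between the tumour groups. Its level therefore does not follow myeloid cells alone. A single library is argued against as the cause, since the median was 0.59, 0.65 and 0.78 without Akt/Nras/Foxo1AAA replicate 1, 2 and 3, although 4, 3 and 13 genes were then called. More resident macrophages stay open beside an effect of Foxo1AAA, a hypothesis, since 3 of 14 Kupffer cell markers rose, in groups that overlapped in the mean of the list (camera adjusted p = 0.00698, adjusted p = 0.453 with an estimated correlation; 13 of the 14 had at least 1 FPKM in normal liver and 2 stood on another list), while the most abundant, C1qa, stood at 134 FPKM in Akt/Nras and 141 FPKM in Akt/Nras/Foxo1AAA tumours. Lymphocytes stay open too, since only 1 of 23 T and NK cell markers and 3 of 15 B and plasma cell markers were measured.

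Of 35 splits of the 7 libraries of normal liver and Akt/Nras tumours 1, the real one, called as many as 8587 genes, and the highest other called 4627. For normal liver and Akt/Nras/Foxo1AAA tumours it was also 1 of 35, with 7874 genes against 3307 at most. Chance assignment of the libraries is argued against for both, at the smallest share that 35 splits can give. Between the tumour groups the real split called 1500 genes and the highest of the others 1, but 10 splits are too few for a share under 0.05.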

How the results depend on the processing

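Alternatives were fixed before the data were examined, except limma-voom on recovered reads, which was added after the data were seen. For Akt/Nras tumours against normal liver, 44 of 55 named genes kept their call and its direction, or stayed not called, in every alternative run. For Akt/Nras/Foxo1AAA tumours against normal liver 32 of 43 did, and between the tumour groups 9 of 47. Those 9 include Akt1, Akt2, Gsk3a, Gsk3b, Tsc1 and Tsc2, which were not called in the main fit. Of the 47, 36 lost their call in some setting and 25 without some single library. Unless a construction is named, the cause of a change was not tested. Depth limits genes near 1 read, worth up to 0.1135 FPKM over 1 kb.

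Leaving out single libraries gave 8007 to 8595 genes (3596 to 3879 higher, 4411 to 4716 lower) for Akt/Nras tumours against normal liver and 7138 to 8100 (3018 to 3450 higher, 4120 to 4650 lower) for Akt/Nras/Foxo1AAA tumours. Between the tumour groups it gave 550 to 1953 (402 to 1247 higher, 148 to 706 lower). The count there was 550 (402 higher, 148 lower) without Akt/Nras/Foxo1AAA replicate 1, 632 (451 and 181) without its replicate 2 and 901 (612 and 289) without Akt/Nras replicate 1, and the lower genes were 291 without Akt/Nras replicate 3 and 333 without normal liver replicate 4. Lists called numbered 38 to 41, 40 to 46 and 33 to 36 in the 3 comparisons, overlaps 2833 to 3103 higher and 3787 to 4050 lower, and the covariance -0.372 to -0.264 (-0.284 without Akt/Nras replicate 1, -0.364 without replicate 3).

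Scaling turned directions. With equal totals 8614 genes were higher and 1714 lower in Akt/Nras tumours than in normal liver, 7613 and 1678 in Akt/Nras/Foxo1AAA tumours, and 650 and 3015 (3665 in all) between the tumour groups, of which 1128 were called in the same direction as without rescaling. With the 50 most abundant genes left out of the scaling the counts were 7489 and 2195, 6845 and 1916, and 803 and 1239. Median-of-ratios scaling changed the counts less, to 4121 and 4429, 3741 and 4059, and 1107 and 447. Of the 8587, 7874 and 1500 genes called without rescaling, 8300, 7389 and 1433 were called in the same direction with it. Quantile normalization gave 4167 and 4414, and 3595 and 4075, against normal liver. It gave 966 higher and 847 lower genes between the tumour groups. Both tumour groups shared 7395 higher and 1447 lower genes with equal totals, and 6453 and 1740 with the 50 genes left out. In Akt/Nras tumours, log2 changes turned positive with equal totals and with the 50 genes left out for Foxo1 (0.62 and 0.35), Tsc2 (0.61 and 0.34) and Dcn (0.37 and 0.11), and with equal totals for Akt2 (0.06). In Akt/Nras/Foxo1AAA tumours that of Tsc2 did (0.46 and 0.32).

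A minimum of 5 FPKM, which tests fewer genes, gave 5372 (1969 higher) and 5027 (1783 higher) against normal liver and 1636 shared higher genes. Between the tumour groups no filter gave 923 (595 higher, 328 lower), a pseudocount of 0.1 gave 305 lower genes, array weights 3668 (1989 and 1679) and only the 2 groups in the fit 10 (5 and 5), with fewer libraries for the spread. Of the genes called between the tumour groups, 347 higher and 78 lower changed by at least 1 on the log2 scale with a pseudocount of 0.1, 179 and 44 with no filter, 216 and 40 with a minimum of 5 FPKM, 215 and 115 with array weights, 137 and 37 with the replicate block, 382 and 151 with voom and 4 and 4 with only the 2 groups in the fit. Voom on recovered reads called 8476, 7643 and 1979 genes, of which 8068, 7155 and 1461 were shared. The covariance was -0.555 with a pseudocount of 0.1, -0.155 with no filter, -0.443 with a minimum of 5 FPKM, -0.409 with equal totals, -0.277 with array weights and -0.661 with voom. With an estimated correlation camera called 0 lists in each comparison (8, 10 and 8 at an unadjusted p under 0.05) and fry called 47, 49 and 28. Called in every other setting were 25 of 40, 27 of 44 and 21 of 34 lists. Scaling turned camera's direction, which is relative to other genes, for the ribosomal protein list against normal liver in both tumour groups, for plasma proteins in Akt/Nras/Foxo1AAA tumours against normal liver and for oxidative phosphorylation between the tumour groups. With equal totals the medians of 10, 6 and 10 of the 56 lists changed sign in the 3 comparisons, among them in Akt/Nras tumours the PI3K (-0.33 to 0.58), interferon (-0.22 to 0.62) and Kupffer cell (-0.33 to 0.28) lists. Median, mean and camera differed in sign for the interferon list in Akt/Nras tumours, for the PI3K, unfolded protein and lysosome lists in Akt/Nras/Foxo1AAA tumours, and for the ATF4, pentose phosphate and p53 lists between the tumour groups.

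With the replicate number as a block (replicate block), limma called 7963, 7238 and 468 genes, the last 332 higher and 136 lower. Deviations from the group means correlated at -0.17 to 0.11 between 9 pairs of libraries with the same number and at -0.15 to 0.2 between 24 other pairs. These correlations showed no pairing by number, but so few pairs cannot exclude a shared litter, day or batch.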

Other observations

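The tests of the sex-biased and clock lists below were fixed before the data were examined, and these lists were picked for description after their results were seen. In Akt/Nras tumours 18 of 19 male-biased liver genes fell, also adjusted over the list alone (camera adjusted p = 1.62e-07, adjusted p = 0.264 with an estimated correlation), and 11 of the 19 stood on another list. Mup21 fell from 1520 ± 26.7 FPKM (SD, n = 4) to 3.91 ± 2.96 FPKM (SD, n = 3). Of 11 female-biased genes 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0166, adjusted p = 0.34 with an estimated correlation), with 5 of the 11 at 1 FPKM or more in normal liver and 2 on another list. The list's call was lost with equal totals (camera adjusted p = 0.368) and with the 50 most abundant genes left out of the scaling (0.238). Cyp2a4 rose from 0.817 ± 1 to 55.3 ± 19.5 FPKM and Cyp17a1, a steroid 17-alpha-hydroxylase, from 0.551 ± 0.235 to 36.8 ± 14.8 FPKM, while Acot3, an acyl-CoA thioesterase, fell from 4.16 ± 3.05 to 1.04 ± 0.106 FPKM. Between the tumour groups 4 male-biased genes, Mup20, C6, Slco1a1 and Nudt7, were higher with Foxo1AAA, and 6 adjusted over the list alone (camera adjusted p = 0.000519, adjusted p = 0.383 with an estimated correlation, limma's fry adjusted p = 0.0595). Of the female-biased genes Cyp2a4 and Cyp2b9 were higher, also adjusted over the list alone. The call of Cyp2a4 was lost without normal liver replicate 4, Akt/Nras replicate 1 or 2 or Akt/Nras/Foxo1AAA replicate 1 or 2 (limma adjusted p up to 0.131). The female-biased list was not called (camera adjusted p = 0.216, adjusted p = 0.64 with an estimated correlation) except with equal totals (0.0306).

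Of 14 circadian clock genes 10 fell and 2 rose in Akt/Nras tumours, with the same counts adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.304 with an estimated correlation). Dbp, a clock output factor, fell from 77.4 ± 19.7 FPKM (SD, n = 4) to 10.4 ± 1.73 FPKM (SD, n = 3). Clock rose from 1.52 ± 0.282 to 2.88 ± 0.229 FPKM, and Cry1, a repressor of the clock, from 5.72 ± 1.61 to 8.59 ± 1.49 FPKM (limma adjusted p = 0.0393). The call of Cry1 was lost without normal liver replicate 1 or 4, Akt/Nras replicate 1 or 2, or Akt/Nras/Foxo1AAA replicate 2 (highest limma adjusted p 0.136, without Akt/Nras replicate 2). The hour at which the samples were collected is not given in the sources used here.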
